A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

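RNA was measured by sequencing in 23 libraries of budding yeast (Saccharomyces cerevisiae) that fell into 8 groups. Per the labels' protocols, cells were grown overnight in rich YPD medium and refreshed for 4 h in YPD at 23 °C in deep-well plates, and total RNA was extracted with a yeast RNA kit. The deposited count table held raw counts per gene, with 1 column per library. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, FastQC 0.11.5, HISAT2 2.0.5, HTSeq 0.6.1p1 and DESeq2 1.14.1, with the genome build R64. Whether counting used strand, and how reads shared between gene copies were handled, is not given in the sources used here. Overlapping genes and members of near-identical families were therefore treated as uncertain.

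The authors' deposited table of a comparison held, per the file headers, a mean normalized count per gene (a signal), a log2 fold change with its standard error, a test score and the p-value columns. Its mean counts differed by at most 0.267% from size-factor-scaled sums of the replicates of the 7 populations without the haploid control, so it was read as a comparison over those 7 populations. Its adjusted p-value column was not the Benjamini-Hochberg adjustment of its p-value column, and the method behind it is not given in the sources used here.

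The count table listed 6596 genes, of which 6531 had a total above 0 and 6111 passed the low-count filter (filterByExpr with the 8 groups). Gene names and R64 coordinates came from the reference table, which matched 5749 of the 6111 tested genes. Libraries held 12719710 to 19327344 counts. The common biological coefficient of variation between replicate libraries was 5.05%, so small changes could be called. The labels do not say that replicate libraries came from separate cultures, so p-values over libraries measure only the spread between these libraries, which may be technical. Replicate pairs were compared by a chi-square test over genes with 10 or more counts, and each pair differed by more than sampling noise, so each library was counted.

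Counts were scaled with TMM and fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by the quasi-likelihood test with 1 coefficient per group and 15 residual degrees of freedom. Contrasts gave the mean of the aneuploid populations of a route against the euploid population of that route, each population against its euploid population, the difference between routes, and the comparisons of the euploid groups. Adjusted p-values are Benjamini-Hochberg values over all tested genes, called at 0.05. Standard errors of log2 fold changes are those implied by the F statistic. A second fit summed the replicates of each population and used the 7 populations as the units, with route and ploidy as terms and 4 residual degrees of freedom. Levels are TMM-scaled CPM (counts per 1e6 counts of a library). A library with 0 counts of a gene still allows up to 3 counts.

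Gene lists (27) were fixed before the data were examined, as were the groups, the designs and the rule for named genes. Lists were tested with camera on a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Of 646 symbols asked by name, 5 were not found in the table and were left out. Chromosome shifts were the median log2 fold change over the tested genes of each chromosome, tested with fry on log2 CPM (prior count 2) over 80 combinations of chromosome and population. The named genes were up to 10 per direction for the tetrad, a-selection and shared results, with average log2 CPM of 3 or more and the same sign in each aneuploid population. Up to 3 per direction were taken for the other contrasts, the 5 smallest p-values for the test among A1, A2 and A3, up to 4 members per list, and every member of the marker and mating-type lists. This rule named 159 genes.

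Alternatives included other scaling factors, DESeq2 1.42.0, other filters, a replicate block, chromosome-centred offsets, only the groups compared, a stricter threshold, leaving out each library and leaving out each aneuploid population. The comparisons of the aneuploid populations with the haploid control were added after the data were seen. Other splits of the libraries were refitted for at most 100 splits per result. For the results that regroup both routes together the number drawn was lowered from 100 to 60 for run time after the first draws had been seen. Splits that keep populations whole were added after the data were seen. The steps were tested on simulated counts for the 6111 genes with 200 changed genes. For the tetrad comparison 75.5%, 89.0% and 91.5% of genes changed by 1.2, 1.5 and 2-fold were recovered, and for the a-selection comparison 80.5%, 91.0% and 91.0%. For the fit with the population as unit, 0.5%, 0% and 50.0% were recovered at the same folds. The real data called far more genes (5179 for tetrad and 4813 for a-selection). The simulations therefore do not test the scaling where most genes change, and these rates may not hold there.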

Results

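Heterogeneous aneuploid yeast populations, in which cells carry different abnormal chromosome sets, were compared with euploid populations to find expression changes that go with aneuploidy. Populations came from 2 routes, tetrad dissection and a-selection. Tetrad dissection gave 1 euploid population and the aneuploid populations T1 and T2, and a-selection gave 1 euploid population and the aneuploid populations A1, A2 and A3. Each of these 7 populations had 3 libraries, and a haploid control had 2. The labels give BY4741, a common laboratory strain, for all 23 libraries. Total counts ran from 12719710 to 19327344 per library. The first principal component held 71.5% of the variance between libraries. On it the haploid control lay at -116 ± 0.400 (SD, n = 2), the euploid populations at 73.5 ± 0.945 (tetrad, n = 3) and 44.0 ± 0.372 (a-selection, n = 3), and the 5 aneuploid populations between them, from -27.0 to 8.33.

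Mating-type and marker genes differed between the groups. MF(ALPHA)1, which encodes the pheromone alpha-factor, was at 2216 ± 8.03 CPM (SD, n = 3) in the euploid tetrad population, 399 ± 8.05 in T1 and 323 ± 15.2 in T2. It was at 1.65 CPM or less in each a-selection population and in the haploid control. The receptor gene STE3 of alpha cells was at 992, 234 and 287 CPM in these populations, and between 3.79 and 7.46 CPM in the other groups. STE3 shares 272 bp with an overlapping gene. URA3, a uracil synthesis gene often deleted as a marker, was at 181 CPM in T1, 141 in T2 and 656 in A1, and at most 0.244 CPM in the other groups. LEU2, a leucine synthesis gene, was at 0.0729 CPM in the haploid control, 66.8 in euploid tetrad, 33.0 in T1 and 18.6 in T2, and 110 in euploid a-selection, 269 in A1, 244 in A2 and 376 in A3. The usual BY4741 genotype is mating type a and lacks LEU2, URA3 and MET17, a methionine synthesis gene. MET17 was at 317 CPM in the haploid control and 12.0 CPM in euploid tetrad, and LYS2 was at 170 and 16.9 CPM. HO, the mating-type switching endonuclease gene, was at 130 CPM in A1 and 3.15 CPM in its euploid population.

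**Figure D1:**
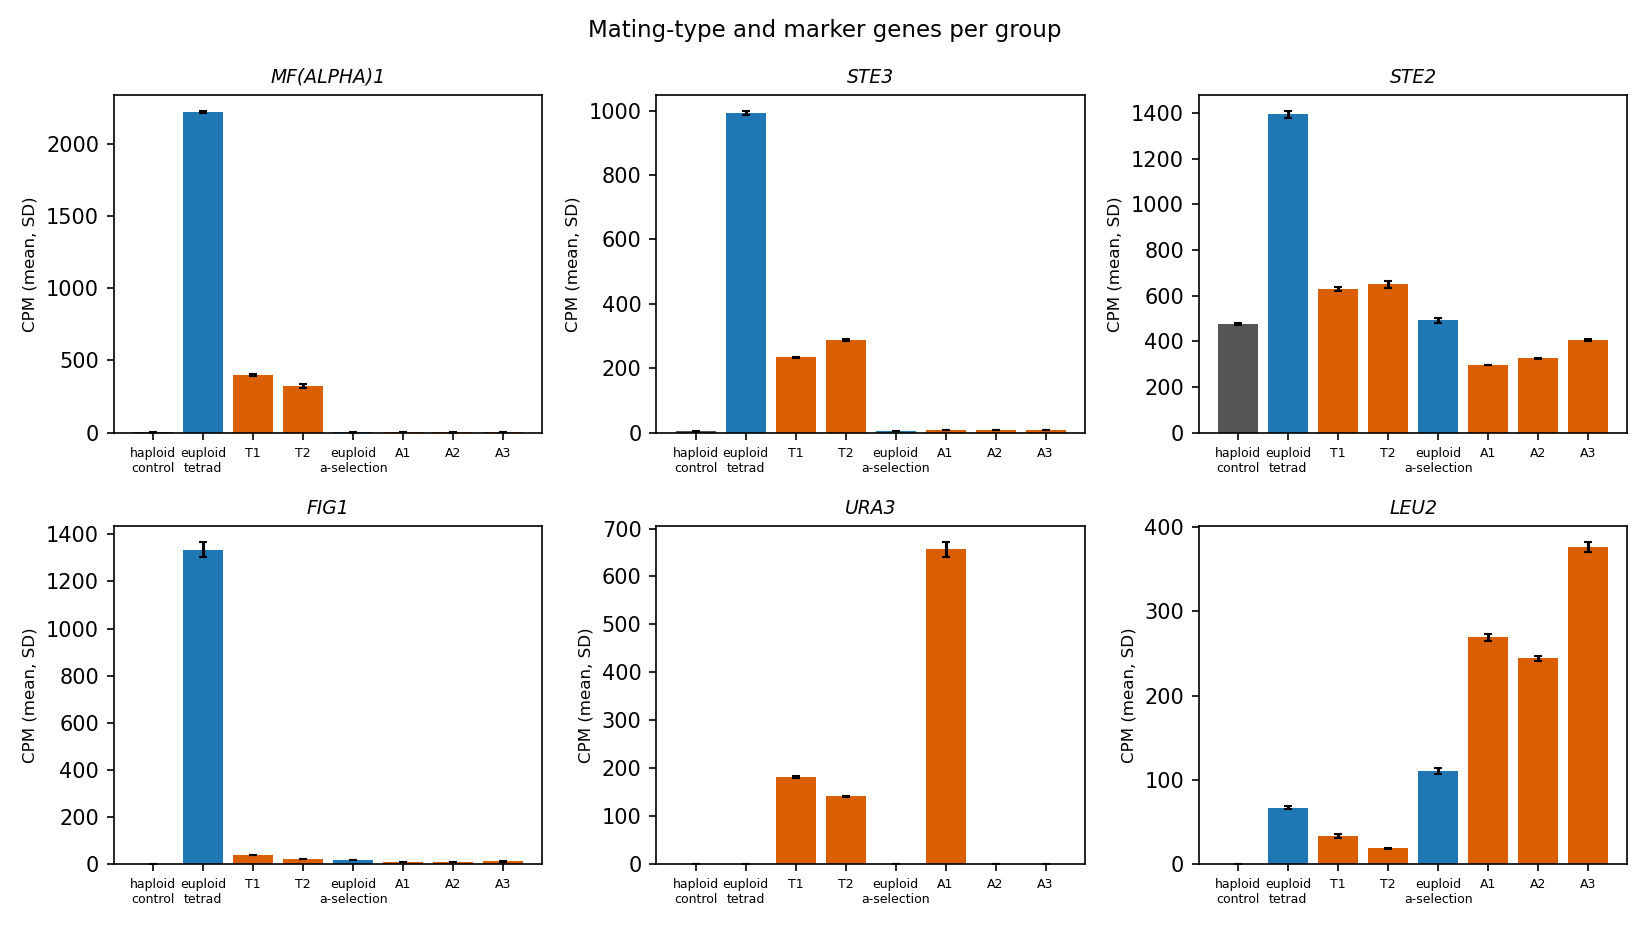
Mating-type genes (MF(ALPHA)1, STE3, STE2), the pheromone-induced gene FIG1 and the marker genes URA3 and LEU2 in the 8 groups; bars are means of TMM-scaled CPM on the y axis and error bars are SD (n = 3, haploid control n = 2). URA3 stands at 656 CPM in A1 and near 0 in A2, A3 and the euploid groups.

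In the tetrad comparison, the aneuploid populations T1 and T2 had much higher levels of ribosome genes and lower levels of stress, respiration and mating genes than the euploid tetrad population. All 52 ribosome biogenesis genes rose, with a median log2 fold change of 3.97, and 136 of 137 cytosolic ribosomal protein genes rose, with a median of 2.66. MAK16, needed for large ribosomal subunit assembly, rose by 6.03 ± 0.19 (SE) on the log2 scale, the helicase gene DBP3 by 5.71 ± 0.12 and NOP1, the fibrillarin gene, by 5.46 ± 0.08. The highest change by the naming rule was in HXT1, a low-affinity glucose transporter gene (YHR094C, chromosome VIII, 290913 to 292625, R64), at 6.66 ± 0.08 (edgeR quasi-likelihood test, adjusted p = 5.63e-27). HXT3, another low-affinity transporter gene, rose by 5.49 ± 0.04.

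Of 32 genes induced in the environmental stress response, 31 fell in the tetrad aneuploids (median log2 fold change -0.99), among them the catalase gene CTT1 (-1.41 ± 0.02) and GND2 of the pentose phosphate pathway (-2.18 ± 0.02). Of 18 targets of the osmotic stress (HOG) pathway 15 fell, with a median of -1.27, led by TDH1 (-3.18 ± 0.02) and the glycerol transporter gene STL1 (-3.11 ± 0.02). CTT1, HSP12, ALD3 and HOR7 belong to both of these lists, so the 2 results are not independent. Of 45 genes of the TCA cycle and respiratory chain 44 fell (median -0.86), with citrate synthase CIT1 at -1.32 ± 0.01. MLS1, the malate synthase gene of the glyoxylate cycle, fell by 4.26 on the log2 scale and the peroxisomal catalase gene CTA1 by 3.76. All 23 haploid-specific and pheromone response genes fell, with a median of -1.82. FIG1, a pheromone-induced gene (YBR040W, chromosome II, 316968 to 317864), had the largest fall by the rule, at -5.57 ± 0.04 (edgeR, adjusted p = 1.08e-31), and PRM3 and PRM2 stood at -4.93 ± 0.08 and -4.49 ± 0.05.

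Other groups in the tetrad aneuploids rose in part. Of 46 amino acid biosynthesis genes under Gcn4, 37 rose and 7 fell (median 0.93), with ILV5 at 3.64 ± 0.03. Of 24 sulfur and methionine genes 18 rose (median 0.72), with the S-adenosylmethionine synthetase gene SAM1 at 4.88 ± 0.04. Of 24 Hsf1 and cytosolic chaperone genes 17 rose and 5 fell (median 0.70), with BTN2 at 3.61 ± 0.03 and the Hsp40 gene YDJ1 at 3.02 ± 0.03. Of 28 G1 and S phase genes 26 rose (median 0.92). By camera, adjusted p was 3.09e-22 for ribosome biogenesis, 3.14e-91 for ribosomal proteins, 7.79e-14 for the stress response, 1.53e-11 for HOG targets, 1.72e-11 for respiration and 9.05e-28 for pheromone genes. It was 1.37e-09 for Gcn4 targets, 0.00103 for sulfur, 9.94e-04 for chaperones and 0.0209 for G1 and S phase. These 10 calls held with an estimated correlation, where the highest adjusted p = 0.0419 (G1 and S phase). The counts of members were the same when adjusted over the list alone.

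Over all genes, 2441 rose and 2738 fell in the tetrad aneuploids (5179 of 6111), of which 969 and 527 changed 2-fold or more. Which direction held more genes depended on the scaling: with upper-quartile factors 2683 rose and 2495 fell. ERR1 also met the naming rule among lower genes, but the T1 libraries held at most 3 counts of it and it belongs to a family of near-identical copies, so no fold is given.

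In the a-selection comparison, A1, A2 and A3 had higher ribosome genes and lower osmotic stress and respiration genes than the euploid a-selection population, with smaller changes than in the tetrad route. All 52 ribosome biogenesis genes rose (median log2 fold change 2.64) and 132 of 137 ribosomal protein genes rose (median 1.32). PWP1, a ribosome biogenesis gene, rose by 4.17 ± 0.06, HXT3 by 4.13 ± 0.03 and the ribosomal subunit assembly gene MRT4 by 4.03 ± 0.07. GRE1 (YPL223C, chromosome XVI, 128632 to 129138), an osmotic stress gene, had the largest fall by the rule at -2.41 ± 0.02 (edgeR, adjusted p = 5.31e-28), and STL1 fell by 2.26 on the log2 scale.

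Of the 18 HOG targets 15 fell in the a-selection aneuploids (median -0.87), of the 32 stress response genes 29 fell (median -0.47), and of the 45 respiration genes 42 fell (median -0.37). Of 17 eisosome and plasma membrane domain genes 14 fell (median -0.35), with PIL1, a core eisosome gene, at -0.62 ± 0.01 and FMP45 at -0.94 ± 0.03. Among 24 chaperone genes 20 rose and none fell (median 0.47), with BTN2 at 2.87 ± 0.03 and YDJ1 at 2.56 ± 0.03. Of 26 ergosterol synthesis genes 22 rose (median 0.41), with ERG11 at 1.66 ± 0.03 and ERG3 at 1.89 ± 0.04. Of 46 Gcn4 targets 39 rose (median 0.68), 40 when adjusted over the list alone. Of 20 hexose transport genes 10 rose and 5 fell (median 0.40). Of 16 glycolysis genes 15 rose (median 0.53), with ENO2, which has a near-identical copy in ENO1, at 3.00 ± 0.04. By camera, adjusted p was 6.08e-35 for ribosome biogenesis, 2.69e-75 for ribosomal proteins, 1.24e-18 for HOG targets, 2.01e-13 for the stress response, 1.14e-08 for respiration, 5.16e-12 for chaperones and 2.83e-08 for Gcn4 targets. It was 4.87e-04 for eisosomes, 1.94e-04 for ergosterol, 0.00719 for hexose transport and 2.51e-06 for glycolysis. All but glycolysis held with an estimated correlation (glycolysis adjusted p = 0.0783 with an estimated correlation).

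Over all genes, 2430 rose and 2383 fell in the a-selection aneuploids (4813 of 6111), of which 674 and 71 changed 2-fold or more. With RLE factors 2362 rose and 2470 fell. YBR116C and TKL2, both lower by the rule at -1.60 ± 0.04 and -1.48 ± 0.02, overlap by 335 bp on the same strand, so their counts are not separate. YLR154C-G, at -2.03 ± 0.59, missed the threshold without A2 (log2 fold change -1.16).

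**Figure D2:**
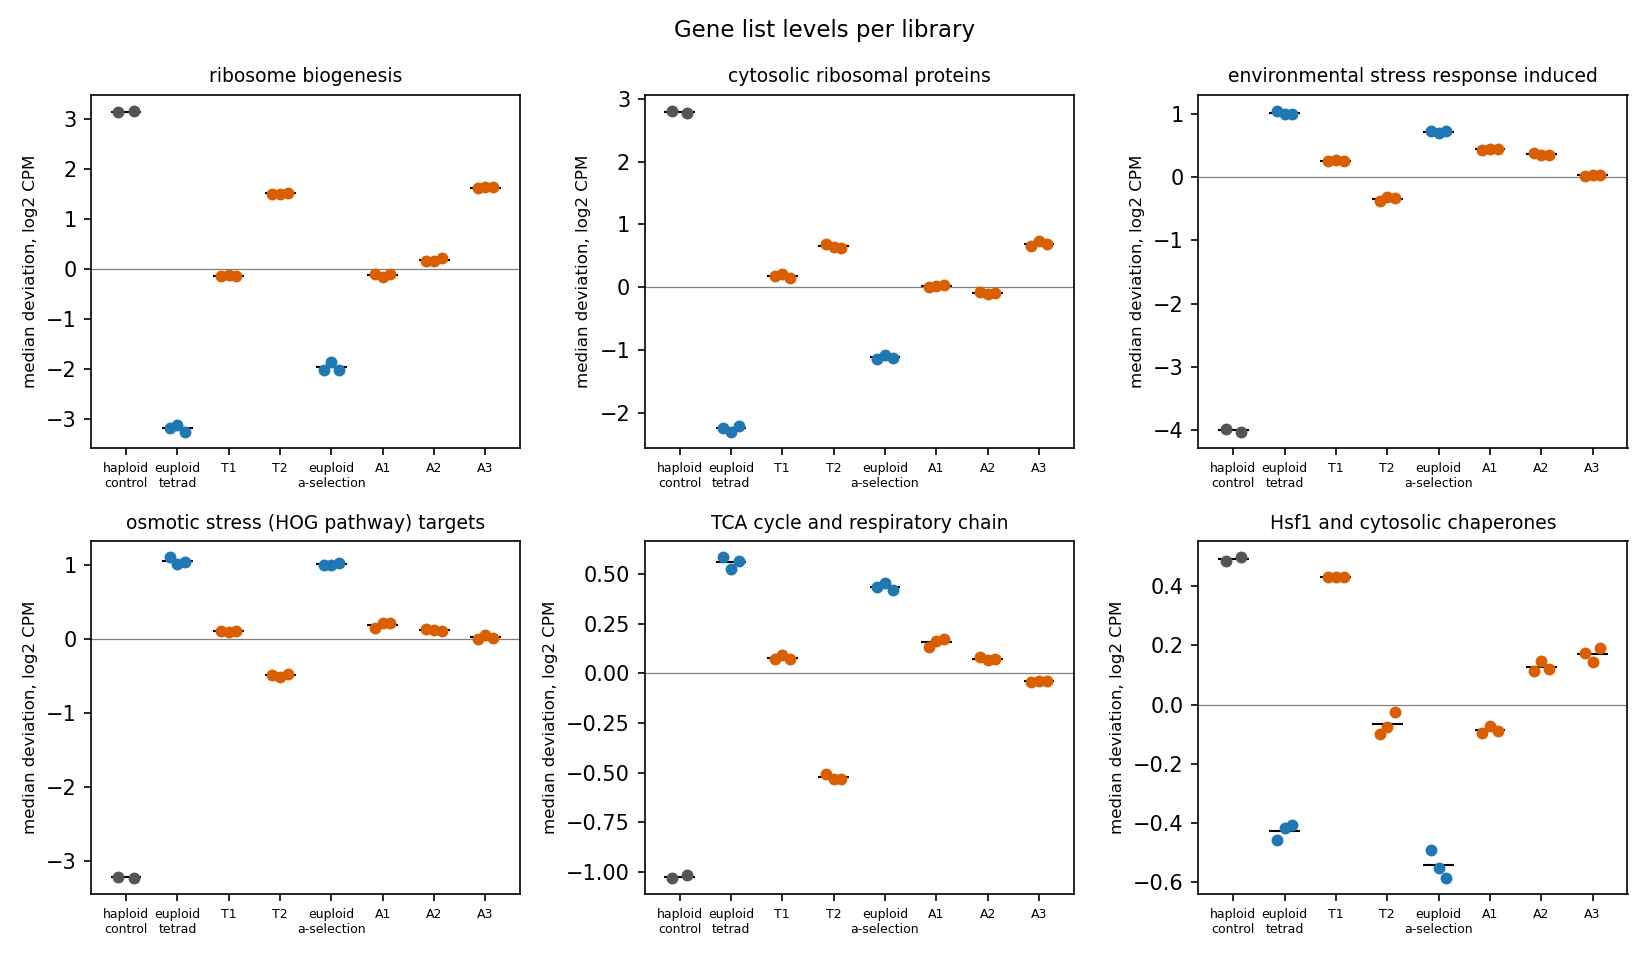
Median deviation of 6 gene lists from each gene's mean over all libraries (log2 CPM, y axis) in the 8 groups; points are libraries and lines group means. Ribosome biogenesis genes stand at 3.15 in the haploid control, -3.18 in euploid tetrad, -1.96 in euploid a-selection and between -0.13 and 1.63 in the aneuploid populations.

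The changes shared by both routes bear on a common aneuploid signature, and the routes share no library. Ribosome assembly genes led the shared rise: PWP1 rose by 5.42 ± 0.07 and 4.17 ± 0.06 (tetrad and a-selection), SYO1 (278 bp shared with an overlapping gene) by 5.05 ± 0.16 and 4.07 ± 0.13, CGR1 by 4.95 ± 0.18 and 4.05 ± 0.14, and RRS1 by 4.83 ± 0.19 and 4.03 ± 0.17. HXT3 rose by 5.49 and 4.13. The shared fall was led by STL1 (-3.11 ± 0.02 and -2.26 ± 0.01), the osmotic stress gene SIP18 (-2.70 ± 0.05 and -1.68 ± 0.04), the stationary phase gene SPG4 (-2.41 ± 0.04 and -1.47 ± 0.03), PHM7 (-2.02 ± 0.02 and -1.47 ± 0.02), and the cell wall mannoprotein gene FIT1 of iron uptake (-1.95 ± 0.05 and -1.43 ± 0.05). In all, 1836 genes rose and 1910 fell in both routes (edgeR, adjusted p under 0.05 in each), where independent lists of these sizes would share 971 and 1068. Another 601 were called in opposite directions. Each route had only 1 euploid population. When whole populations were regrouped, another split gave up to 1798 genes alike, against 2866 in the real split refitted that way. The overlap therefore does not separate aneuploidy from other differences between the euploid and aneuploid cultures. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.790 and a slope of 0.487 for a-selection on tetrad.

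**Figure D3:**
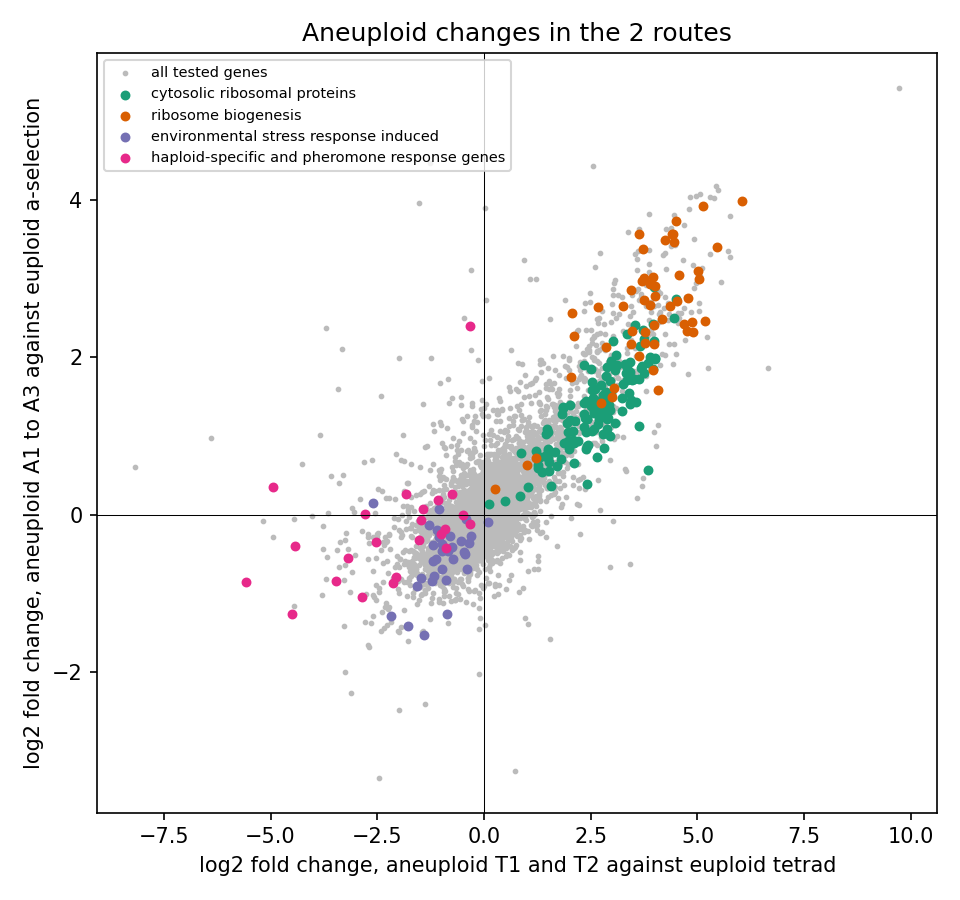
Log2 fold change of each tested gene in the tetrad comparison (x axis) and the a-selection comparison (y axis); colours mark 4 gene lists. Ribosome biogenesis genes have medians of 3.97 and 2.64, and pheromone genes -1.82 and -0.25.

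The change against the euploid population differed between routes in mating and glycolysis genes and in single genes such as HXT1, and so did the euploid populations themselves. HXT1 rose by 6.66 in tetrad and 1.86 in a-selection aneuploids, a difference of 4.80 ± 0.10 (edgeR interaction contrast, adjusted p = 2.42e-21), where euploid a-selection was already 4.41 above euploid tetrad. HPF1, a cell wall gene, differed by 3.61 ± 0.06, PRM3 by -5.29 ± 0.19, and DPA10 by -6.06 ± 0.24. All 23 pheromone genes had a lower change in the tetrad route, by a median of -1.50, and 13 of 16 glycolysis genes did, by a median of -1.03. Between the euploid populations, a-selection against tetrad, the medians of these lists were -4.21 and -1.36. In this test 4377 genes differed between the routes, of which 771 differed 2-fold or more. Its p-values measure the spread between libraries, not between populations. When whole populations were regrouped, 5 of 12 splits gave as many genes (2560 in the real split, 4662 at most in another). A difference between routes therefore cannot be told apart from differences between single populations.

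The single populations ranged in the size of their change. Against their euploid population, 4959 genes changed in T1 and 5187 in T2, and 4423, 4413 and 4882 in A1, A2 and A3, where 2-fold changes numbered 1244, 1788, 587, 606 and 1122. MAK16 rose by 7.17 ± 0.17 in T2, and RRS1, NOG1 and RPF2, all ribosome biogenesis genes, rose by 5.87 ± 0.15, 5.53 ± 0.09 and 5.47 ± 0.09 in A3. HO (5.37 ± 0.07) and DPA10 (3.96 ± 0.21) rose in A1, where CPA1 of arginine synthesis and its upstream reading frame YOR302W fell by 2.11 and 2.30 on the log2 scale. COS3, named in T2, belongs to a multicopy family and lost its call without 1 library (highest adjusted p = 0.795, edgeR). T2 exceeded T1 in the nucleolin-like gene NSR1 (2.99 ± 0.04, 584 of its 1245 bp shared with an overlapping gene), TRM11 (2.72 ± 0.10) and AAH1 (2.59 ± 0.05), and T1 exceeded T2 in the heat shock genes SSA4 (-2.34 ± 0.03 for T2 against T1) and HSP30 (-1.90 ± 0.04), with 4220 genes differing. Among A1, A2 and A3, 4510 genes differed (edgeR F test of 2 contrasts), led by URA3, HO, GPP1, NSR1 and ILV5. ILV5 stood at 1.47, 1.43 and 3.16 against the euploid population in A1, A2 and A3.

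The euploid populations lay far from the haploid control. All 52 ribosome biogenesis genes were lower and all 32 stress response genes higher in euploid tetrad than in the haploid control, with medians of -6.52 and 5.19. In euploid a-selection against the haploid control the medians were -5.16 and 4.85. STL1 was higher by 11.69 ± 0.05 in euploid tetrad and MAK16 lower, at -9.31 ± 0.15. In these comparisons 5540 and 5467 genes differed (edgeR), of which 3381 and 3108 differed 2-fold or more. Upper-quartile scaling moved the euploid tetrad comparison by -0.11 for all genes. Against the same haploid control the aneuploids too were lower in ribosome biogenesis genes (52 of 52, medians -2.49 for tetrad and -2.65 for a-selection) and higher in all 32 stress genes (4.03 and 4.27), opposite in sign to their change against the euploid populations. Between the euploid populations 4314 genes differed, with RPS8B (4.05 ± 1.07, a duplicated ribosomal protein gene whose call was lost without 1 library) and HXT1 (4.41 ± 0.10) higher in a-selection and PRM6, which shares 242 bp with an overlapping gene, lower (-8.09 ± 0.08).

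With each population as the unit (5 aneuploid, 2 euploid), ribosome genes again rose. Of 137 ribosomal protein genes 124 rose and of 52 ribosome biogenesis genes 44 rose, with median log2 fold changes of 1.92 and 3.48, and 11 of 18 HOG targets fell. In all 869 genes rose and 671 fell (edgeR, smallest adjusted p = 0.00993). Camera called these lists, but with an estimated correlation no list passed (lowest adjusted p = 0.558 with an estimated correlation). The count fell to 3, 3, 0 and 1 without T1, T2, A2 and A3 (2608, 2459, 2470 and 2380 genes at an unadjusted p under 0.05, edgeR). With no route term, edgeR called 0 genes with the haploid control as another euploid population (244 genes at an unadjusted p under 0.05) and 1558 without it. The authors' deposited table called 222 genes by its adjusted p column, 169 higher and 53 lower in the aneuploids, where a Benjamini-Hochberg adjustment of its p column gave 2525. In the authors' deposited table, 37 ribosomal protein genes, 16 ribosome biogenesis genes, 7 chaperone genes and 4 hexose transport genes were higher, and 5 HOG targets and 5 pheromone genes lower. Of the 222 genes of the authors' deposited table, 220 were called alike in both routes and 219 in the population fit. Over all 6111 tested genes these numbers were 3746 and 1540. Both sides rest on the same counts, so the overlap is not independent evidence.

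Genes of chromosome VIII were higher in the a-selection aneuploids. Its 292 tested genes had a median log2 fold change of 0.40 in A1, 0.47 in A2 and 0.46 in A3, with 86.3%, 89.0% and 77.4% of genes positive (fry adjusted p = 6.82e-22, 8.52e-23 and 5.13e-23, and camera against the other genes 5.77e-12, 1.07e-14 and 2.93e-07, limma). Chromosome XI was also higher in A1, A2 and A3 (medians 0.18, 0.26 and 0.24, camera adjusted p = 0.00141, 2.61e-06 and 0.00893). Chromosome VI was lower in the same populations (medians -0.10, -0.15 and -0.26, camera adjusted p = 0.00861, 0.00351 and 0.0269). Its medians in T1 and T2 were lower still (-0.30 and -0.31), with camera adjusted p = 0.0678 and 0.105. The euploid populations stood above the haploid control on chromosome VI (medians 0.26 for a-selection and 0.44 for tetrad, camera adjusted p = 0.945 and 0.936). Chromosome I was higher in A1 and A2 (0.15 and 0.22, camera adjusted p = 0.0421 and 0.0119). In A3, T1 and T2 its medians were negative (-0.094, -0.15 and -0.24, camera adjusted p = 0.284, 0.335 and 0.355). In T1 chromosome IV was lower (median -0.23, camera adjusted p = 0.0232), and in T2 its median was -0.27 (camera adjusted p = 0.0612). Fry asks whether the genes of a chromosome change on average beyond the spread between libraries, without comparing them with other genes. It called 74 of 80 combinations of chromosome and population. Camera called 12, of which T1 had 1 and T2 had 0 (2 at an unadjusted p under 0.05), where fry called 16 in T2.

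**Figure D4:**
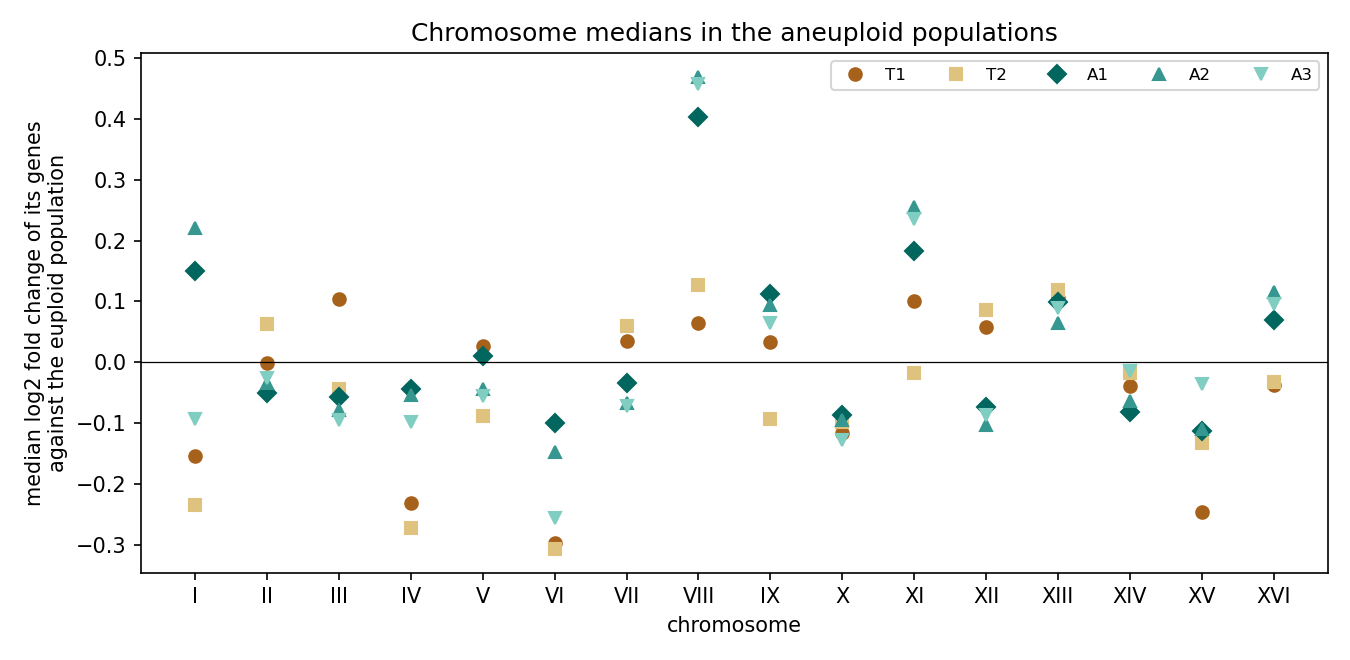
Median log2 fold change of the tested genes of each chromosome (x axis) in the 5 aneuploid populations against their euploid population (y axis). Chromosome VIII stands at 0.40, 0.47 and 0.46 in A1, A2 and A3, and at 0.06 and 0.13 in T1 and T2.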

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

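Tests of the first pattern, of the mating genes and of the chromosome VIII level of the euploid population were chosen after the results were seen; the tests of chromosome arms, of residuals and of splits over libraries were chosen before. The groups had 2 or 3 libraries, too few for a test of single outlying libraries. The items below differ between routes by the interaction contrast, which also holds the difference between the euploid populations. In all 4377 of the 6111 tested genes did (71.6%), and 150 of the 159 named genes. Most named genes were picked for their changes in these same data, so their higher share is built in.

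Relative to the a-selection route, the tetrad aneuploids had a higher change (median of the difference, log2) in cytosolic ribosomal proteins (1.25), ribosome biogenesis (1.23), sulfur and methionine (0.54), G1 and S phase genes (0.47), iron regulon (0.41), Gcn4 targets (0.40), proteasome (0.24) and phospholipid and fatty acid synthesis (0.24). They had a lower change in alpha-specific genes (-2.97), haploid-specific and pheromone response genes (-1.50), glycolysis (-1.03), a-specific genes (-0.59), oxidative stress genes (-0.50), HOG targets (-0.47), respiration (-0.46) and the stress response (-0.39). With an estimated correlation these calls were lost, at adjusted p = 0.0569 for the stress response and for G1 and S phase, 0.0621 for Gcn4 targets, 0.109 for iron, 0.0589 for phospholipids, 0.0620 for the proteasome, 0.0610 for oxidative stress and 0.0649 for alpha-specific genes. Low levels limit the alpha-specific result. In euploid a-selection MF(ALPHA)1, MF(ALPHA)2 and STE3 were at 0.606, 0.426 and 4.50 CPM, so they had little room to fall. In euploid tetrad they were at 2216, 1926 and 992 CPM. SAG1, the other alpha-specific gene, was at 73.8 and 2725 CPM in these populations. Among named genes HXT1 differed by 4.80, HPF1 by 3.61, DPA10 by -6.06 and PRM3 by -5.29. In all, 15 named genes were called in opposite directions, among them MLS1 (-4.26 and 0.65) and CPA1 (1.04 and -1.39). Under other settings some were not stable: HXK2 in tetrad was 0.031 without T1, and in a-selection DSE3 and PCL2 were -0.11 and -0.051 without A1, while CDA1 without A1 and MF(ALPHA)1 without A3 lost the call (edgeR, adjusted p = 0.327 and 0.376).

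The first pattern is that the aneuploid libraries lay between the haploid control and the euploid populations along ribosome and stress genes. Scaling is argued against, since a factor moves all genes of a library alike, while the medians of ribosome biogenesis and stress response genes in the tetrad comparison had opposite signs and lay 4.95 apart. Ploidy class alone is argued against for the whole pattern, since euploid tetrad differed from the euploid haploid control by a median of -6.52. The haploid control also differed in marker genes, so this does not bear on aneuploidy as the cause within a route. A growth-state axis shared by the routes may account for part of it. The tetrad change had a Pearson correlation across genes of -0.768 with euploid a-selection minus haploid control, which shares no library with it. In a linear regression on this axis, median residuals of ribosome biogenesis genes were 1.40 (tetrad) and 1.07 (a-selection). Those of stress response genes were 0.93 and 0.26. Ribosome biogenesis genes thus rose more than a linear axis predicted, while stress response genes fell less. For these lists the values argue against a linear axis as the whole cause. Whether aneuploidy set the growth state of the cultures, or the cultures were sampled at different states, stays open because no growth measure was analysed here, and marker genes differ too: URA3 in T1, T2 and A1 and LEU2 in all 5 aneuploid populations against their euploid populations, and LEU2 in the haploid control.

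The second pattern is the fall of mating and pheromone genes in the tetrad aneuploids. Fewer alpha cells and lower expression per cell cannot be told apart: the 4 alpha-specific genes fell by a median of -2.28, but the 7 a-specific genes fell too (median -0.92). More a/alpha diploid cells as the whole cause is not decided. HO, NEJ1 and STE5, which diploids repress, had a median of -0.33 against -1.82 for the list. But the list also holds pheromone-induced genes such as FIG1, which less pheromone signalling could lower further. Less pheromone signalling between the cells stays open as an untested alternative.

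The third pattern is chromosome VIII in the a-selection aneuploids. A low level in the euploid a-selection population is not decided by its median of -0.052 against the haploid control, where genes went both ways (47.3% positive, mean -0.20). Against euploid tetrad its median was -0.0028, so the level was not low relative to that population. After a linear regression on the growth-state axis, chromosome VIII genes kept a median residual of 0.32 in a-selection. The residual alone cannot decide whether they follow that axis, since ribosome biogenesis genes, which lie along it, kept 1.07. But euploid tetrad minus haploid control, the axis used, had a chromosome VIII median of only -0.049 (48.6% of genes positive). The tetrad aneuploids had a larger ribosome biogenesis rise (median 3.97 against 2.64), yet chromosome VIII medians of only 0.06 in T1 and 0.13 in T2. These values argue against that axis as the whole cause of the chromosome VIII rise. Extra copies of the whole chromosome in a share of cells may account for it: both arms were higher, and the lowest of the 6 arm medians was 0.33. No DNA measurement was analysed here, so this stays a hypothesis.

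Other splits of the libraries, each refitted on the libraries compared, do not decide on chance here. Libraries are nested in populations, so splits that mix them set differences between populations against the spread between replicate libraries. Splits that keep populations whole, which were added after the data were seen, are too few for a share under 0.05: 3 for tetrad, 4 for a-selection and 12 for both routes together. With whole populations the tetrad split gave 4440 genes against 2350 at most in another split (T2 against the rest), the a-selection split 3762 against 3201, genes changed alike 2866 against 1798, and gene list calls 31 against 29. For the difference between routes 5 of the 12 whole-population splits gave as many genes (2560 in the real split, 4662 at most in another), and for chromosome calls 4 of 12 did (74 and 77). These splits point to large differences between single populations.

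Over all library splits, 1 of 84 gave as many genes for tetrad, the real one (2350 at most in another), 1 of 100 for a-selection (57 at most in another), 1 of 100 for A1, A2 and A3 (4569 against 3597) and 1 of 100 as many chromosome calls (16 at most in another). Of 60 draws that regrouped both routes, 1 gave as many genes changed alike (0 at most in another), 1 as many differing between routes (61) and 2 as many list calls (31 in each). Comparisons of 3 libraries with 3 allow only 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: the real counts were 4861 for T1, 5062 for T2, 4331 for A1, 4379 for A2, 4862 for A3, 4188 for T2 against T1 and 4106 for the euploid populations, and in each the highest other split gave 0.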

How the results depend on the processing

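The 2-fold threshold and the comparisons of the aneuploids with the haploid control were added after the data were seen. So were the fits of the 7 populations without a route term. The other alternatives were chosen before. Outside the 2-fold threshold, the counts of changed genes in fits of single libraries stayed within 1.5 times of the reported counts under each scaling, filter, test, threshold and set of libraries tried. With a change of 2-fold or more also required, the counts were 1496 for tetrad, 745 for a-selection, 771 for the difference between routes, 629 changed alike, 1244 for T1, 1788 for T2, 587 for A1, 606 for A2, 1122 for A3, 425 for T2 against T1 and 672 between the euploid populations. Against the haploid control they were 3381 (euploid tetrad), 3108 (euploid a-selection), 2420 (tetrad aneuploids) and 2557 (a-selection aneuploids).

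The population fit was the least stable. From 1540 genes it moved to 3 without T1, 3 without T2, 0 without A2 (2470 at an unadjusted p under 0.05) and 1 without A3, and it was 1308 without A1. With the haploid control as another euploid population and no route term edgeR called 0 genes (244 at an unadjusted p under 0.05). DESeq2 called 2518 on the same populations, and 2367 with no route term. With RLE factors, chromosome-centred offsets, a log2 CPM floor of 3 and no route term edgeR called 1588, 1473, 1523 and 1558. The cause of these changes was not tested.

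Leaving out each library in turn gave 5059 to 5159 genes for tetrad, 4588 to 4796 for a-selection, 3620 to 3738 changed alike and 4218 to 4374 differing between routes. The ranges were 4824 to 4848 for T1, 5081 to 5129 for T2, 4219 to 4263 for A1, 4243 to 4303 for A2, 4740 to 4785 for A3, 4046 to 4096 for T2 against T1 and 4308 to 4434 among A1, A2 and A3. They were 5377 to 5498 for euploid tetrad against the haploid control, 5322 to 5429 for euploid a-selection against it, 5170 to 5400 and 5218 to 5452 for the tetrad and a-selection aneuploids against it, and 4137 to 4196 between the euploid populations. List calls stayed at 30 and chromosome calls at 72 to 77. Among single named genes, calls of COS3 in T2, DSE3, ENO1, MF(ALPHA)1 and PCL2 in a-selection, HXK2, OYE2 and ERR1 in tetrad, ERR1 in T1, ERR1 and URA3 in the difference between routes, and RPS8B between the euploid populations were lost without at least 1 library.

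Fry in place of camera called 51 list results against 30, and camera in place of fry called 12 chromosome results against 74. Fry asks whether the genes of a set change on average, without comparing them with other genes. In 17 chromosome results called by fry, with a negative median, the direction of camera was opposite to that of fry: XVI in T1 (median -0.037), X and XVI in T2 (-0.098 and -0.033), II, VII and XII in A1 (-0.051, -0.035 and -0.073), II and V in A2 (-0.034 and -0.045), and in A3 II (-0.026), III (-0.094), IV (-0.098), V (-0.055), VII (-0.072), X (-0.13), XII (-0.087), XIV (-0.014) and XV (-0.036). These medians do not carry a direction.

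Of the named gene results outside single-library omission 3346 kept direction and call, 26 lost the call, 8 gained it and 13 changed sign, with the cause not tested. HXK2 in tetrad was 0.027 with upper-quartile scaling and 0.031 without T1. With chromosome-centred offsets RPN2 in a-selection was -0.0073, OYE2 in tetrad -0.019 and PRM4 in a-selection -0.10. OYE2 in tetrad was -0.086 without T2. In a-selection, PRM4, PCL2 and DSE3 were -0.11, -0.051 and -0.11 without A1, ENO1 and DSE3 were 0.026 and -0.043 without A2, and ENO1 and CTA1 were 0.083 and 0.37 without A3.

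The replicate numbers did not pair the libraries: of 77 same-numbered pairs 23 had a correlation of deviations over 0.1, the range was -0.31 to 0.38, and 5 libraries matched their own number best. With a replicate block the counts were 5171 for tetrad, 4807 for a-selection, 3733 changed alike and 4360 between routes. List calls were 29, since hexose transport in tetrad missed the threshold (camera adjusted p = 0.0674).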

Other observations

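Cell wall and membrane lists had members going both ways. Of 29 cell wall integrity genes 20 rose and 6 fell in tetrad (median log2 fold change 0.26, camera adjusted p = 0.0180) and 22 rose and 5 fell in a-selection (0.45, adjusted p = 6.70e-04), and these calls were lost at adjusted p = 0.251 and 0.141 with an estimated correlation. GAS1, a cell wall glucan remodelling gene with an overlapping neighbour, rose by 2.58 ± 0.02 (SE) and 1.63 ± 0.02, and the glucan synthase gene FKS1 by 2.64 ± 0.04 and 0.89 ± 0.03. In tetrad 13 of 17 eisosome genes fell (median -0.36, adjusted p = 0.0124, and adjusted p = 0.0918 with an estimated correlation). Of 23 phospholipid and fatty acid genes 17 rose and 5 fell in tetrad (0.49, adjusted p = 0.0399, and adjusted p = 0.133 with an estimated correlation), and 9 rose and 11 fell in a-selection (-0.05, camera adjusted p = 0.698). ELO3, which elongates fatty acids, rose by 4.16 ± 0.08 and 2.05 ± 0.06. Ergosterol genes in tetrad missed the threshold (18 of 26 higher, 7 lower, median 0.29, camera adjusted p = 0.0692).

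Nutrient lists moved less uniformly, and the values here are tetrad first and a-selection second. Of 20 phosphate genes 11 rose and 6 fell, then 15 and 4 (medians 0.26 and 0.34, camera adjusted p = 0.461 and 0.104), with the phosphate transporter PHO84 at 1.92 ± 0.03 and 1.73 ± 0.03. Of 29 nitrogen and amino acid transport genes 12 rose and 16 fell, then 10 and 16 (medians -0.14 and -0.20, adjusted p = 0.160 and 0.104), with the amino acid permease DIP5 at -2.58 ± 0.02 and -1.04 ± 0.01 and PUT4 at -2.22 ± 0.02 and -1.17 ± 0.02. Of 27 iron genes 15 rose and 8 fell, then 12 and 11 (medians 0.25 and 0.05, adjusted p = 0.143 and 0.246), where the second median was positive and the camera direction down. For 20 hexose transport genes in tetrad 7 rose and 9 fell, with a negative median (-0.34) but camera direction up (adjusted p = 0.0358, and adjusted p = 0.0622 with an estimated correlation). The rise was carried by HXT1, HXT3, HXT4 (4.11 ± 0.03) and HXT2 (4.03 ± 0.03), while HXT5 fell (-1.58 ± 0.02). Glycolysis in tetrad was mixed (7 of 16 higher, 9 lower, median -0.14, adjusted p = 0.619), as were sulfur genes in a-selection (12 of 24 higher, 6 lower, median 0.10, adjusted p = 0.104).

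Protein quality, mating and cell cycle lists gave the remaining values by camera. Proteasome genes were 23 higher and 6 lower of 33 in tetrad and 10 and 18 in a-selection (medians 0.22 and -0.07, adjusted p = 0.154 and 0.353). Unfolded protein response genes were 10 higher and 6 lower of 18 in both routes (medians 0.20 and 0.07, adjusted p = 0.174 and 0.312), with the Hsp70 gene KAR2 at 1.42 ± 0.02 and 1.21 ± 0.02. Yap1 targets were 6 higher and 11 lower of 21 in tetrad (-0.12, adjusted p = 0.0415, and adjusted p = 0.324 with an estimated correlation) and 10 and 10 in a-selection (-0.02, camera direction up, adjusted p = 0.353). All 7 a-specific genes fell in tetrad (median -0.92, adjusted p = 9.95e-05) and in a-selection (-0.38, adjusted p = 0.0203, and adjusted p = 0.0927 with an estimated correlation). In A3 only 5 of the 7 fell, while MFA1 and MFA2 rose (0.27 and 0.33), and their a-selection calls were lost without A1 (edgeR, adjusted p = 0.536 and 0.182) and without A2 (0.0791 and 0.0779). The 4 alpha-specific genes fell in tetrad (-2.28, adjusted p = 2.88e-10), while in a-selection 2 were higher and 1 lower (median 0.68, camera direction down, adjusted p = 0.750). The higher genes were at low levels in the a-selection populations: MF(ALPHA)1 at 0.588 to 1.65 CPM, near the detection floor, and STE3 at 4.50 to 7.46 CPM. SAG1, the lower gene, was well above the floor, at 73.8 CPM in euploid a-selection and 46.8 to 51.1 CPM in A1 to A3. Pheromone genes in a-selection were 5 higher and 13 lower of 23 (-0.25, adjusted p = 0.0977). Meiosis genes were 4 higher and 11 lower of 24, then 10 and 6 (medians -0.20 and 0.21, camera direction down in both, adjusted p = 0.192 and 0.577). G1 and S phase genes in a-selection were 21 higher and 5 lower of 28 (0.32, adjusted p = 0.0777), and M and early G1 genes 9 and 9 of 21, then 14 and 2 (medians 0.0046 and 0.14, adjusted p = 0.812 and 0.333, with camera direction down in tetrad).

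A hypothesis stated before its test was that the cell wall and chaperone lists respond to aneuploidy beyond the growth-state axis. Each route's change was regressed across genes on the difference of the other route's euploid population from the haploid control, which held 59.0% of the variance in tetrad and 56.1% in a-selection. The smallest of the 4 median residuals was -0.15 (chaperones, tetrad), and neither list was higher than other genes in its residuals in both routes (cameraPR adjusted p = 0.367 and 0.141 for cell wall, 0.740 and 3.03e-04 for chaperones), so what the hypothesis predicted was not seen in both. Ribosome biogenesis (median residuals 1.40 and 1.07), hexose transport (0.82 and 0.74) and the stress response (0.93 and 0.26) had positive residuals in both. For the stress response this means a smaller fall than the axis predicted, since its genes fell in both routes. Hexose transport in tetrad also had a negative median change, so its residual there does not mean that most members rose. The residuals of the routes had a Pearson correlation across genes of 0.161. They share libraries, and both regression slopes were negative (-0.436 in tetrad and -0.226 in a-selection). The haploid control, held by both regressors, can therefore raise this correlation. The euploid libraries, which each regressor takes from the other route, can lower it.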
